A study of Mus musculus with 12 samples.

How the data were processed

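Peak lists from 12 libraries were analysed, 1 per condition: 4 ChIP-seq libraries (BAP1 and ASXL1, each with 1-590 and 10RA) and 8 H2AK119ub CUT&RUN libraries (4 in the 1-590 set and 4 in the 1-1067 set). Groups, comparisons and batches follow the sample labels. Peak names inside the 25RA, 34DN and 36EQ lists carry other codes than the sample titles, so which mutant each of these values belongs to rests on the titles. Libraries were compared within a batch: 12 pairs within batches, plus the overlap of BAP1 with ASXL1, of ChIP with H2AK119ub, and of the vector libraries of the sets, which come from different batches. Per the labels' descriptions the ChIP used antibodies to BAP1 or ASXL1, whereas the labels' protocols name an antibody to the HA tag. Peaks are called BAP1 or ASXL1 by the name of the library.

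Per the submitters' processing notes, the tools were fastp 0.24.0, Bowtie2 2.5.4, SAMtools, Picard and MACS3 3.0.3, with the mm39 genome. Each deposited list gives a fold enrichment at the summit over the local background, which the authors' peak caller made as a ratio of fragment pileup plus 1 to background plus 1. The -log10 p and -log10 q of each summit are the authors' caller's own and were made within each library. The score is, as deposited, the whole part of 10 times -log10 p, in all but 10 of 160204 peaks. The lists reach p of 0.001 with no q threshold: the largest q in a list ran from 13.1% to 51.4%. These fold and -log10 values were used to describe, rank or filter peaks within a list and to recover fragment pileups and backgrounds, from which depth was compared between libraries; fold and -log10 values themselves were not compared between lists. Per the labels the CUT&RUN data were normalized with E. coli spike-in reads. Whole fragment numbers were recovered from the fold and p of 100% of peaks in each of the 12 lists. The peak calls thus rest on whole fragments, not on pileups multiplied by a spike-in factor. Whole numbers cannot show whether fragments were subsampled to a spike-in scale before calling. If they were, the recovered depth carries that scale. Use of a control library is not stated in the labels.

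Peaks on chromosomes 1 to 19, X and Y were used, and no regions within them were excluded. Coordinates are GRCm39, counted from 1. Against that assembly 0 peaks ran past a chromosome end and 0 lay in assembly gaps of 10 kb or more. Genes were the 21738 protein-coding genes of GENCODE vM39, and a promoter was 2 kb on each side of the canonical TSS. Libraries share a peak where intervals overlap by 1 base or more. Random overlap is the mean of 100 random placements of the peaks. Wilson 95% intervals cover counting error only. The 16 gene lists (Hox genes, HSPC and leukaemia regulators, myeloid, erythroid and megakaryocyte, lymphoid, mast cell and basophil, and stromal and endothelial genes, developmental regulators of other lineages, cell cycle inhibitors and tumour suppressors, Polycomb subunits, BAP1 complex and partners, cytokine and JAK-STAT signalling, interferon-stimulated genes, ribosomal proteins, MYC and growth genes, olfactory receptors) were written from general knowledge, and 388 of 389 requested symbols were found, olfactory receptors being taken from the annotation. Percentiles place a list's count among 10000 random lists matched for CpG content in 10 groups (1001-base window), ties split evenly.

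Named genes follow a rule: per pair and direction, the 8 genes with the largest promoter peak fold among those with a peak in one library and none in the other; the 5 strongest peaks of each ChIP library by fold; members of the 16 lists; and Bap1, Asxl1, Cdkn2a and the Hoxa genes always. Genes under 1 shared peak are named together. Some genes under this rule are not reported here.

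Depth per library was read from the lowest background of its peaks, in fragments per base, given at the start of the report. To match depth, summit pileups were thinned at random to the lowest background in the batch and their p recomputed, 20 draws, at p of 0.001, 1e-05, 1e-06 and 1e-08. Tested on simulated data in 16 settings, the thinned list held 69.7% to 138% of the peaks called after thinning the fragments themselves, and this range is the error of the thinning; the lowest setting was strong signal at the strictest p. The settings with few peaks had as few as 5 called. Depth matching of gene counts carries no such error term. Overlap, percentile, copy number and pileup functions were also tested on simulated data, with overlap counts equal to those of bedtools.

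The groups, the comparisons, the alternatives of overlap, promoter width, list length, strict q and fold, covered bases, merged peaks, all sequences and unmatched random lists were fixed before the data were examined. The filter at q of 0.05, depth matching at each p, and the simulations behind it were chosen after the data were seen. Copies of sequence were counted as the median number of genome occurrences of the 32-base words of a region. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. Raw reads were not used here, so signal outside peaks was not measured.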

Results

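The data were 12 lists of peaks from mouse c-Kit+ bone marrow cells, a fraction enriched for haematopoietic stem and progenitor cells (HSPCs), that carried a retrovirus for BAP1 together with a retrovirus for ASXL1 or an empty vector. BAP1 is the deubiquitinase that removes ubiquitin from histone H2A, ASXL1 is its cofactor, and H2AK119ub is the ubiquitinated form of H2A that Polycomb repressive complex 1 lays down. Truncating ASXL1 mutations occur in myeloid malignancies. The study asked how truncated ASXL1, and mutations that alter its condensation, change where BAP1 and ASXL1 sit on chromatin and where H2AK119ub lies. The 1-590 set held ASXL1 residues 1 to 590, the forms 10RA (condensation-impaired per the labels) and 25RA (condensation-defective per the labels), and a vector control. The 1-1067 set held residues 1 to 1067, the charge-neutralized forms 34DN and 36EQ, and its own vector control. H2AK119ub was mapped by CUT&RUN, in which a nuclease tethered to an antibody releases the marked fragments, in all 8 conditions. BAP1 and ASXL1 were mapped by ChIP-seq in the 1-590 and 10RA conditions, 4 libraries in all. Each condition had 1 library, so no difference between conditions below has a replicate check, and percentiles and random placements describe the libraries only.

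On chromosomes 1 to 19, X and Y, the BAP1 lists held 3572 peaks with 1-590 and 4875 with 10RA, and the ASXL1 lists held 8370 and 4584. The H2AK119ub lists of the 1-590 set held 20124 peaks in vector, 32495 in 1-590, 28228 in 10RA and 33863 in 25RA. Those of the 1-1067 set held 5742 in vector, 6310 in 1-1067, 5307 in 34DN and 6084 in 36EQ. The peak lists were unequal in depth: the genome background recovered from them was 4.24 and 5.46 fragments per base for BAP1 with 1-590 and 10RA, and 4.99 and 3.04 for ASXL1. It was 0.908 in vector, 2.06 in 1-590, 1.72 in 10RA and 1.86 in 25RA, and 2.92 in vector, 2.17 in 1-1067, 2.59 in 34DN and 2.84 in 36EQ. Peak numbers are therefore given as listed and after each list was thinned to the lowest background of its set.

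**Figure D1:**
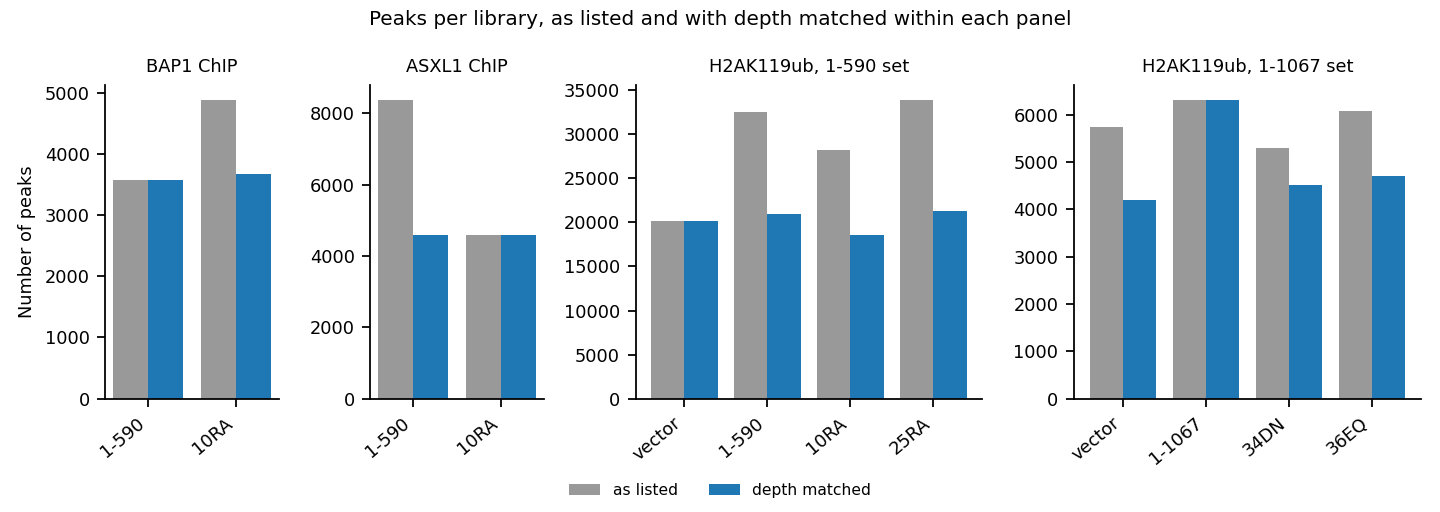
Number of peaks per library (vertical axis, from 0) as listed (grey) and after thinning to the lowest background in the panel (blue), for the BAP1 ChIP, the ASXL1 ChIP and the H2AK119ub libraries of the 1-590 and the 1-1067 sets; each bar is 1 library. In the 1-590 set the construct libraries list 28228 to 33863 peaks against 20124 in vector, and 18574 to 21324.5 when depth is matched.

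H2AK119ub peaks were enriched at promoters, and the ChIP peaks as listed were not. Promoters, taken as 2 kb on each side of the transcription start site (TSS) of 21738 protein-coding genes, make up 3.09% of the genome. They held 42.2% of H2AK119ub summits in the vector of the 1-590 set (Wilson 95% interval 41.5 to 42.9), 38.3% in 1-590 (37.8 to 38.8), 31.8% in 10RA (31.3 to 32.4) and 31.6% in 25RA (31.1 to 32.1). In the 1-1067 set the shares ran from 23.7% in vector (22.6 to 24.8) to 27.1% in 1-1067 (26.0 to 28.2). Among the peaks of that set with q of 0.05 or less they were 40.2% in vector (37.6 to 42.9), 38.4% in 1-1067 (36.3 to 40.5), 42.1% in 34DN and 42.3% in 36EQ. Of BAP1 summits, 70 of 3572 (1.55 to 2.47%) lay at promoters with 1-590 and 2.03% (1.67 to 2.47) with 10RA, and of ASXL1 summits 2.57% (2.25 to 2.93) and 1.99% (1.62 to 2.43). Between 59.7% and 65.1% of ChIP summits lay outside protein-coding genes.

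The BAP1 ChIP compared 1-590 with 10RA, to ask whether impaired condensation moves BAP1. The strongest peaks were at the same places in both. By the fold enrichment over background that the authors' peak caller gave each peak, the leading BAP1 peak with 1-590 lay at chromosome 11, 3122327 to 3122876 (GRCm39), in an intron of Sfi1, with a fold of 17.7. The next lay at chromosome 9, 123290885 to 123291252, in an exon of Lars2, the mitochondrial leucyl-tRNA synthetase, with a fold of 17.4. The same intervals led in 10RA, with folds of 21.6 at Sfi1 and 15.1 at Lars2, together with an interval between genes at chromosome 9, 3006760 to 3007758, with a fold of 18.0. The Sfi1 and Lars2 peaks, and one at chromosome 3, 5925408 to 5925874, were also listed in all 8 H2AK119ub libraries. The chromosome 9 interval between genes was listed in 9 of the 12 libraries. Peaks also listed with another antibody and method cannot show whether BAP1 itself moved. Of all 3572 peaks with 1-590, 4.06% met a peak in 10RA (3.46 to 4.76), against a mean of 0.123% in 100 random placements. Among peaks with q of 0.05 or less the share was 25.2% (21.3 to 29.5).

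Few genes had a BAP1 peak at the promoter, 79 with 1-590 and 120 with 10RA, of which 13 had one in both. With q of 0.05 or less these numbers were 14, 23 and 9. Those listed with 1-590 and not with 10RA included Spink14 (fold 3.43), the olfactory receptor gene Or4c125 (3.34), the somatostatin gene Sst (3.30), Dpm3 (3.24), Magea6 (3.24), Pcdha8 (3.15), Capn6 (3.12) and Mbd3l1 (3.08). Of these, Dpm3, Magea6, Pcdha8, Capn6 and Mbd3l1 had a q above 0.05. Those listed with 10RA and not with 1-590 included the olfactory receptor gene Or6c5 (3.201), Zdhhc25 (3.19), the adenosine receptor gene Adora2b (3.09), Tcp10c (3.07), Tex28 (3.07), Or5p5 (3.04), Aox2 (3.02) and the neuropeptide Y receptor gene Npy5r (3.001). None of the 16 fixed gene lists except the olfactory receptors had a member with a BAP1 promoter peak in either library, and neither Bap1 nor Asxl1 had a ChIP peak. The 10RA list was 1.36 times as long as the 1-590 list and 1.03 times when depth was matched, which the error of the thinning cannot tell from 1. The matched ratio was also undetermined at p of 1e-05 (0.919) and 1e-06 (1.07), and at 1e-08 it was 1.43, above 1 beyond that error, on 129 against 90 peaks. The lower bound of that ratio was 1.04. Depth was matched on background, 1.29 times as high with 10RA. Fragment number, taken as background over the shortest peak length, was 1.48 times as high and was not matched.

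The ASXL1 ChIP compared the same constructs. Its leading peaks were again the interval on chromosome 9, 3006752 to 3007402 (fold 24.2 with 1-590), and those at Sfi1 (22.9) and Lars2 (20.1). ASXL1 peaks without a BAP1 counterpart lay at Kdm6a, which encodes an H3K27 demethylase, and at Pgk1, which encodes a glycolytic kinase. The Kdm6a peak, in an exon at chromosome X, 18120250 to 18120778, had a fold of 19.1 with 1-590 and 21.4 with 10RA and was listed in no other library. The Pgk1 peak with 10RA, at chromosome X, 105230342 to 105230828 and 158 bases from the TSS, had a fold of 19.7. It was listed in both ASXL1 libraries, in the 3 construct libraries of the 1-590 set and in 36EQ. Of the 4584 peaks with 10RA, 4.95% (4.36 to 5.62) met a peak in 1-590, against 0.158% in random placements, and 30.2% (26.3 to 34.4) did among peaks with q of 0.05 or less.

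Promoter peaks for ASXL1 were listed at 231 genes with 1-590 and 99 with 10RA, 15 of them in both. Only the 1-590 list had a promoter peak at Kdm6a (fold 5.34), the lectin gene Clec2e (3.67), the angiotensin receptor gene Agtr1b (3.54), Hnrnpul2 and its neighbour Ttc9c (3.50, 1 shared peak), Or5h24 (3.50), Tmsb4x (3.45) and Eno1b (3.42). Only the 10RA list had one at Kmt2a, the H3K4 methyltransferase rearranged in acute leukaemia (chromosome 9, 44792167 to 44792573, fold 9.40), the ferritin heavy chain gene Fth1 (4.27), Tex11 (3.91), Pxdn (3.83), Mansc1 (3.73), G3bp2 (3.71), Qrfpr (3.51) and Dennd6a (3.47). The promoter of Kmt2a also had an H2AK119ub peak in all 4 libraries of the 1-590 set. Of the fixed lists other than olfactory receptors, members with an ASXL1 promoter peak were Hoxc6 (2.59), Ctsg (2.54), Ermap (2.67), Ebf1 (2.95), Rag2 (2.45) and Mx2 (2.68), all with 1-590. At matched depth the mean counts with 1-590 in these lists ran from 0.25 (Hox genes) to 0.85 (lymphoid genes). The 10RA list was 0.548 times as long as the 1-590 list and 1.00 times when depth was matched.

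BAP1 and ASXL1 peaks of one construct were also compared. With 1-590, 4.14% of BAP1 peaks (3.54 to 4.85) met an ASXL1 peak, against 0.188% at random, and with 10RA 4.14% of ASXL1 peaks (3.61 to 4.76) met a BAP1 peak, against 0.0971%. With q of 0.05 or less in both lists these were 25.4% (21.5 to 29.7) and 27.3% (23.5 to 31.4). Few ChIP peaks as listed carried H2AK119ub. With 1-590, 1.204% of BAP1 peaks (0.895 to 1.62) met an H2AK119ub peak of the same construct, close to the 0.964% of random placements, and 164 of 8370 ASXL1 peaks did (1.68 to 2.28%), against 0.844%. With 10RA the shares were 1.89% for BAP1 (1.54 to 2.31) and 1.42% for ASXL1 (1.11 to 1.80), against 0.715% and 0.613%. Among peaks with q of 0.05 or less in both lists the shares were higher: 8.78% for BAP1 and 6.08% for ASXL1 with 1-590, against 1.08% and 0.856% at random, and 5.28% and 8.83% with 10RA, against 0.670% and 0.647%. Peaks with 10RA met H2AK119ub peaks of the 1-590 library at 6.67% for BAP1 and 11.1% for ASXL1, against 0.966% and 0.879% at random. These higher shares go with higher random overlap, since that list covers 13.1 Mb and the 10RA list 9.02 Mb. H2AK119ub peaks of vector were met by 5.08% and 3.04% with 1-590, against 0.589% and 0.440% at random. With 10RA they were met by 4.15% and 7.19%, against 0.474% and 0.444%. The shares thus do not by themselves tie the mark to the construct. Of 60 BAP1 peaks with 1-590 and -log10 q of at least 5, 52 met a peak in any H2AK119ub library and 49 in all 4 ChIP libraries. These lists hold many weak peaks: a q of 0.05 or less was reached by 12.1% and 16.3% of BAP1 peaks and by 16.9% and 10.6% of ASXL1 peaks.

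H2AK119ub with 1-590 was then compared with its vector, to ask what the truncated protein does to the mark. The pileups were not multiplied by a spike-in factor, and earlier subsampling to such a scale cannot be told from them. A rise or fall of the mark over the whole genome was therefore not measured. Promoter peaks were listed at 12003 genes with 1-590 and at 8799 in vector. Of these, 8141 genes had one in both, 3862 only with 1-590 and 658 only in vector. When depth was matched, 2726 genes had a promoter peak only with 1-590 and 1518.5 only in vector (means of 20 draws). Of the 20124 peaks in vector, 54.2% (53.5 to 54.9) met a peak of the 1-590 library, against 1.04% at random.

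Genes with a strong promoter peak in 1-590 and none in vector were Cenpw, which encodes a centromere protein (chromosome 10, 30076261 to 30076692, fold 9.54), Ngdn (9.45), Stam (9.31), Sde2 (8.95), Spty2d1 (8.85), Crebl2 (8.50), and Nosip with its neighbour Prrg2 (8.21). The reverse held at Tmsb4x, the thymosin beta gene (chromosome X, 165990116 to 165990526, fold 13.02 in vector). It also held at the histone genes H2ac23 and H4c17 (7.34, 1 shared peak), Celf4 (6.85), the peroxiredoxin gene Prdx4 (6.07), Rplp2-ps1 (6.004), Cmtm2a (5.99) and Ptx3 (5.79).

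Hox genes, the homeobox genes of the 4 Hox clusters and classical Polycomb targets, had a promoter peak at 25 of 39 members with 1-590 and at 16 in vector. All 16 were also listed with 1-590, and the 9 further genes were Hoxa3, Hoxa9, Hoxa11, Hoxb1, Hoxb8, Hoxc9, Hoxd1, Hoxd10 and Hoxd11. Hoxa9, a driver of leukaemic self-renewal, had a fold of 2.29 and Hoxd1 a fold of 3.80. Among HSPC and leukaemia regulators, 25 of 32 had a promoter peak with 1-590 and 11 in vector, all 11 shared. The 14 others included Meis1 (fold 2.46), Runx1 (2.63), Gata2 (2.06), Myc (3.09), Erg (2.75) and Lmo2 (3.77), transcription regulators of stem cells and leukaemia. The vector count of 11 lay at percentile 1.68 of 10000 random lists matched for promoter CpG content, and the 1-590 count at 86.3. The vector percentile was 32.9 with promoters of 5 kb on each side and 24.8 of lists not matched for CpG content. Depth-matched means were 18.6 Hox genes and 20.75 HSPC regulators with 1-590.

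Ribosomal protein genes were covered almost in full with 1-590, at 45 of 47 promoters against 31 in vector, all 31 shared. Among the 14 others were Rps2 (fold 4.48), Rplp0 (5.02) and Rpl24 (6.54). The depth-matched mean with 1-590 was 40. Of 20 MYC and growth genes, all had a promoter peak with 1-590 and 12 in vector, with Cdk4 (3.53), Mcm2 (4.07), Mcm5 (3.95) and Fbl (3.65) among the 8 others. Cytokine and JAK-STAT genes counted 20 of 25 with 1-590 (percentile 99.2) and 12 in vector. The 9 listed only with 1-590 included Jak2 (4.48), Jak3 (4.61), Stat5a (3.86) and Il6 (5.09), and Csf2 was listed only in vector.

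Interferon-stimulated genes counted 12 of 20 with 1-590 (percentile 99.8) and 8 in vector, and Mx1 (fold 2.95), Ifit1 (2.60) and Ifih1 (3.84) were among the 5 listed only with 1-590. When depth was matched the mean with 1-590 was 8.7 genes, at percentile 94.3, against 8 in vector at percentile 96.9. The percentile with 1-590 was 65.7 of lists not matched for CpG content. Cell cycle inhibitors and tumour suppressors counted 12 of 14 with 1-590 and 7 in vector. The 5 others were Trp53 (fold 6.24), Rb1 (4.16), Cdkn1a (4.92), Nf1 (2.55) and Cdkn2a (3.36), which encodes p16 and p19Arf. Cdkn2a (chromosome 4, 89192708 to 89212890) had 3 peaks in vector in the gene or within 2 kb of it, none of them at the promoter. Bap1 itself had a promoter peak in all 4 libraries of the set (fold 4.71 with 1-590), whereas Asxl1 had one with 1-590 (4.14) and 25RA (3.89) but not in vector or 10RA.

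Developmental regulators of other lineages counted 29 of 48 with 1-590, at percentile 0.285, and 21 in vector, at 2.73. At matched depth the counts did not differ, with a mean of 21.4 for 1-590 (draws 16 to 24). With promoters of 5 kb on each side the percentiles were 15.9 and 41.3, and of lists not matched for CpG content 76.5 and 67.9. As listed, the genes divided both ways: 14 were listed only with 1-590, Isl1 (fold 3.59), Gata4 (2.37) and Gata6 (2.78) among them, and Pax3, Hand1, Neurog1, Foxa2, Tbx5 and Cdx2 only in vector. The peaks at these genes stood on a high local background. At promoters with a peak the median local background, in multiples of the library's genome background, was 9.21 for Hox genes and 6.47 for developmental regulators with 1-590, against 2.47 for all genes. In vector the values were 8.04, 6.62 and 2.73. A high local background lowers the chance that a narrow peak is called on broad signal, so a missing peak is not a missing mark. Nor does a listed peak measure the amount of mark. At ribosomal protein promoters with a peak the median local background with 1-590 was 2.24, below that of all genes. With no control library stated, whether such peaks reflect the mark alone was not tested.

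Myeloid genes counted 13 of 27 with 1-590, at percentile 99.4 of matched random lists, at 95.02 when depth was matched and at 23.6 of lists not matched for CpG content. They counted 10 in vector, at percentile 98.9 of matched random lists, and a mean of 9.95 with 1-590 when depth was matched. Irf8, Cebpe, S100a8 and Fcgr3 were listed only with 1-590 and Camp only in vector. Erythroid and megakaryocyte genes counted 8 of 21 and 6, lymphoid genes 11 of 24 and 5, and mast cell and basophil genes 7 of 13 and 5. Depth-matched means with 1-590 were 5.35 (draws 4 to 7), 8.9 (7 to 10) and 4.45 (3 to 7). The erythroid and mast cell draws thus spanned the vector counts. Stromal and endothelial genes, markers of cells that a c-Kit+ fraction should mostly lack, counted 8 of 16 and 7. Their depth-matched mean with 1-590 was 6.65 (draws 5 to 8). Polycomb subunits counted 24 of 30 and 18, with Rnf2 and Kdm2b among the 7 listed only with 1-590 and Ezh1 listed only in vector. Genes of the BAP1 complex and its partners counted 11 of 12 in both, with Asxl1 only in 1-590 and Ogt only in vector. Olfactory receptors, silent in blood cells, counted 12 of 1194 with 1-590 and 10 in vector, below all random lists. Depth-matched means with 1-590 were 20.05 for Polycomb subunits and 9.4 for BAP1 complex genes. For olfactory receptors the mean was 5.35 (draws 3 to 7), below the vector count.

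**Figure D2:**
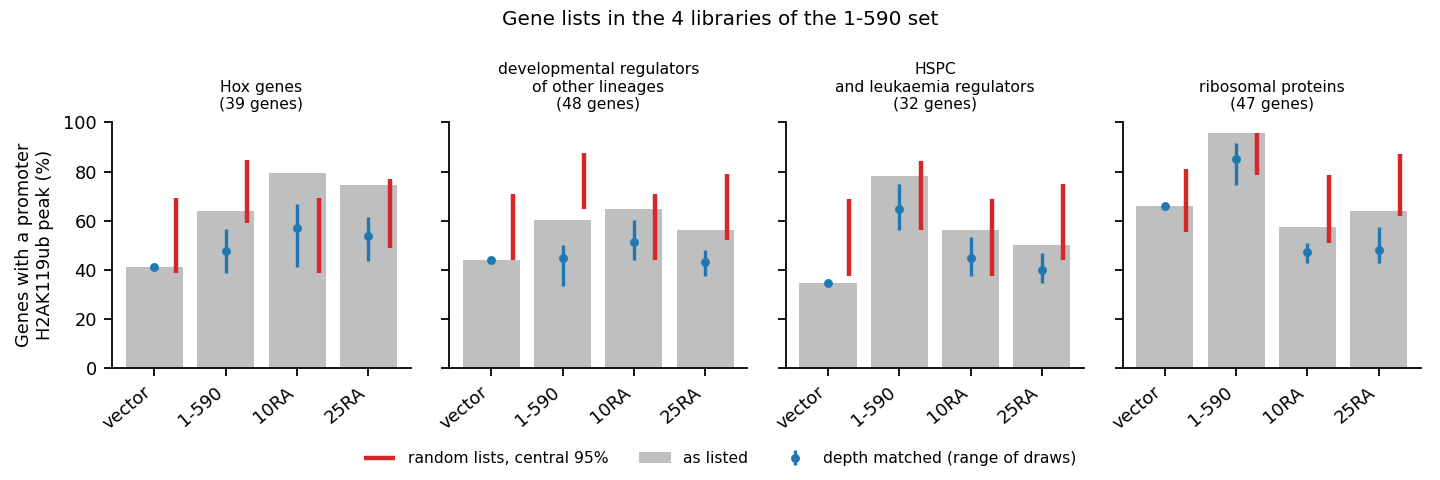
Percent of genes with a promoter H2AK119ub peak (vertical axis, 0 to 100) for 4 gene lists in the 4 libraries of the 1-590 set. Grey bars are the lists as deposited, and blue points the mean after depth matching with the range of 20 draws. Red lines are the central 95% of 10000 random lists matched for CpG content. They were made at the depth as listed, so they belong to the grey bars and not to the blue points. Hox genes reach 31 of 39 in 10RA and 29 in 25RA against 25 in 1-590 and 16 in vector, whereas ribosomal protein genes number 45 of 47 in 1-590, 27 in 10RA and 30 in 25RA.

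The 10RA and 25RA forms were compared with 1-590, to ask which changes depend on condensation. Fewer promoters had a peak with either form: 8989 genes with 10RA and 10401 with 25RA, against 12003 with 1-590. Genes listed only with 1-590 numbered 3998 against 984 only with 10RA, and 2805 against 1203 only with 25RA. Depth-matched means were 4219 against 1268 for 10RA and 3400 against 1527 for 25RA. Against vector, 10RA had 2406 genes of its own and lacked 2216, and 25RA had 3035 and lacked 1433. When depth was matched both turned around, to 1618 against 3362 for 10RA and 1987 against 2653 for 25RA.

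Promoters with a strong peak in 1-590 and none in 10RA were Eif2a and Serp1 (chromosome 3, 58432727 to 58433492, fold 10.96, 1 shared peak), Dhx38 and Txnl4b (10.0, shared), Fra10ac1 (9.89), Scaf8 (9.18), the ubiquitin-conjugating enzyme gene Ube2d2a (8.82) and the RNA helicase gene Dhx16 (8.67). All 8 had a promoter peak in 25RA and in vector. Listed in 10RA and not in 1-590 were L1td1 (fold 6.01), Necab1 (5.40), Slc35f1 (5.14), Tk2 (5.14), Ak5 (5.10), Akr1e1 (5.09) and Or5an6 (5.004). Of these, all except Or5an6 were also listed in 25RA.

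Promoters with a strong peak in 1-590 and none in 25RA were Cenpw (9.54), Mtmr3 (8.65), Atxn3 (8.39), Pet100 and Xab2 (8.04, shared), Airim and the mitosis gene Cdca8 (7.88, shared) and Rabgap1 (7.85). Listed in 25RA and not in 1-590 were Zfp951 (6.64), H2ac23 and H4c17 (6.30, shared), Nxph2 (5.95), Tmsb4x (5.93), Cd200 (5.83), the proteasome subunit gene Psmd14 (5.59) and Ccl27a (5.54). Of these 8 genes, all except Zfp951 also had a promoter peak in vector.

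As listed, more Hox genes had a promoter peak with both forms than with 1-590. A peak was listed at 31 of 39 with 10RA (percentile 99.98 of matched random lists) and at 29 with 25RA (94.8), against 25 with 1-590 (9.64). Hoxa4, Hoxa10, Hoxb9, Hoxc6 and Hoxc12 were listed with both forms and not with 1-590, Hoxa6 with 10RA only and Hoxa2 with 25RA only. Hoxc9 was listed with 1-590 and not 10RA, and Hoxc10, Hoxd11 and Hoxa3 with 1-590 and not 25RA. When depth was matched the counts overlapped between libraries: a mean of 18.6 genes with 1-590 (draws 15 to 22), 22.3 with 10RA (16 to 26, percentile 92.5) and 20.9 with 25RA (17 to 24, percentile 67.4). The 10RA percentile was 61.9 when promoters were taken as 1 kb on each side. Median local background at Hox promoters with a peak ran the other way: 7.27 times the genome background with 10RA, 6.41 with 25RA and 9.21 with 1-590. At all promoters with a peak it was 2.16, 2.22 and 2.47. A larger number of Hox genes with a peak is therefore not a measure of more mark there. Within 105 kb from Hoxa2 to Hoxa13 (chromosome 6, 52137599 to 52242822) the lists hold 2 peaks in vector, 13 in 1-590, 14 in 10RA and 12 in 25RA, counts that were not depth matched.

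**Figure D3:**
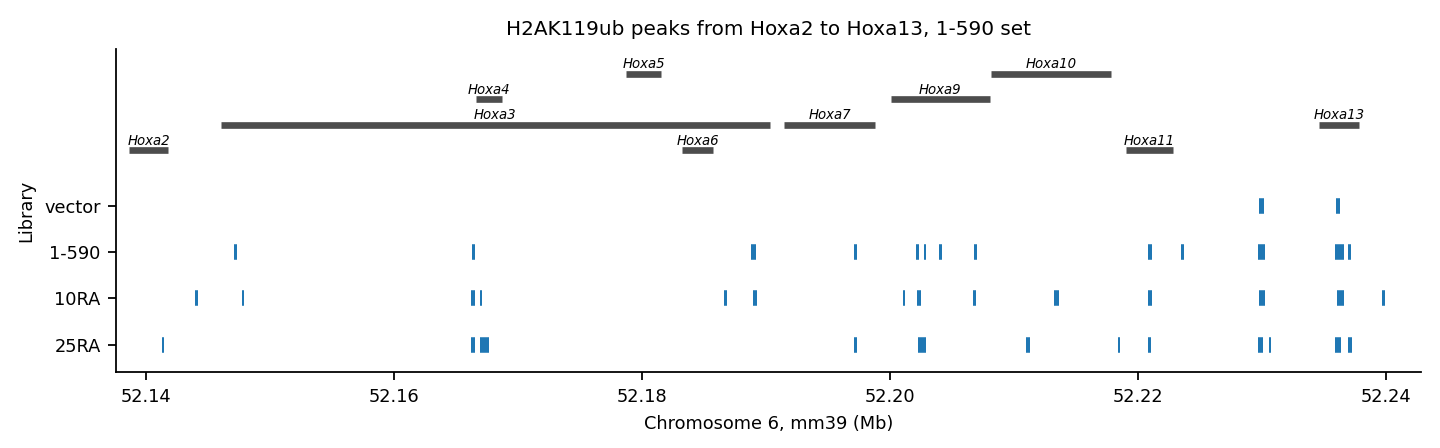
Map of chromosome 6 from Hoxa2 to Hoxa13 (horizontal axis, position in Mb in GRCm39) with gene bodies in grey and the H2AK119ub peaks of each library of the 1-590 set in blue, 1 line per library. Vector has 2 peaks in the window and the 3 construct libraries have 13, 14 and 12.

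Housekeeping and signalling lists had fewer members with a peak in both forms than in 1-590, as did all genes together (8989 and 10401 against 12003). Ribosomal protein genes counted 27 with 10RA and 30 with 25RA, against 45 with 1-590. Rps2, Rplp0, Rpl19 and Rps18 were among those missing from both. MYC and growth genes counted 14 with each form against 20, and Cdk4 and Mcm5 were missing from both. HSPC regulators counted 18 and 16 against 25: Meis1, Runx1, Erg and Procr were missing from both, Gata2 and Lmo2 from 10RA, and Myb, Mecom and Fli1 from 25RA. Cytokine genes counted 12 and 14 against 20, with Tnf, Jak3 and Cish missing from both, and interferon-stimulated genes 6 and 8 against 12, with Ifit1, Mx1, Ifih1 and Irf9 missing from both. Depth-matched means for ribosomal protein genes were 22.15 with 10RA and 22.55 with 25RA, against medians of 24.7 and 28.45 in CpG-matched random lists. For MYC genes they were 10.5 and 11.75 (random 10 and 11.75), and for HSPC regulators 14.3 and 12.8 (13 and 15). For cytokine genes they were 7.4 and 9.75 (9 and 11), and for interferon-stimulated genes 4.35 and 6.3 (4 and 4.35). With 1-590 each list's mean lay above its random median, at 40 against 36 for ribosomal protein genes.

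Developmental regulators counted 31 with 10RA and 27 with 25RA against 29 with 1-590, and members went both ways. Hand1, Neurog1, Tbx5, Wt1 and Myod1 were listed with both forms and not with 1-590, and Isl1, Pax6, Sox17 and Lhx1 with 1-590 and neither form. Polycomb subunits counted 16 and 21 against 24, BAP1 complex genes 8 and 10 against 11, cell cycle inhibitors 9 and 11 against 12, myeloid genes 10 and 11 against 13, and lymphoid genes 8 and 11 against 11. Erythroid genes counted 4 and 7 against 8, mast cell genes 5 and 3 against 7, stromal genes 5 and 8 against 8, and olfactory receptors 17 and 24 against 12. Cdkn2a kept a promoter peak with 10RA (fold 2.88) and 25RA (2.45).

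Over the 4 libraries, 14032 genes had a promoter peak somewhere: 5813 in all 4, 1229 only in 1-590, 454 only in 10RA, 641 only in 25RA and 269 only in vector. A peak in vector, 10RA and 25RA but not in 1-590, as listed and not depth matched, was found at 151 genes and 537 of 72226 regions. Peak numbers at a matched depth relative to vector were 1.04 for 1-590, 0.923 for 10RA and 1.06 for 25RA at the authors' p cutoff of 0.001. At p of 1e-08 they were 0.829, 0.292 and 0.385, the 10RA and 25RA values below 1 beyond the error of the thinning.

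In the 1-1067 set, 31.8% of H2AK119ub peaks in 1-1067, 27.5% in 34DN, 32.7% in 36EQ and 22.8% in vector reached a q of 0.05 or less. Promoter peaks were listed at 2003 genes with 1-1067 and 1617 in vector, 587 of them in both, 1416 only with 1-1067 and 1030 only in vector. At matched depth the counts were 1493 and 814. Peaks with 1-1067 numbered 1.10 times those of vector as listed and 1.502 times at matched depth, above 1 beyond the error of the thinning, and 3.08 times at p of 1e-08. Of vector peaks, 11.1% (10.4 to 11.99) met a peak of the 1-1067 library, against 0.164% at random.

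Promoter peaks in 1-1067 and not in vector were led by the Mediator gene Med16 (chromosome 10, 79744193 to 79744769, fold 6.34), Pnn (5.27), Atp6v1d and the translation initiation gene Eif2s1 (5.10, shared), Cyth2 (5.05), Dhdds (4.97), the splicing gene Srsf5 (4.93) and Fndc8 (4.83). In vector and not in 1-1067 they were led by Cnot4 (4.95), the kinase gene Map2k4 (4.57), Coa6 (4.55), the cohesin loader gene Mau2 and Sugp1 (4.46, shared), the tumour suppressor kinase gene Stk11 (4.36), Pilra (4.35) and Cenpk (4.30). Few list members were reached, and those named here were not filtered on q. With q of 0.05 or less, 953 genes had a promoter peak with 1-1067 and 652 in vector. Hoxd13 (fold 2.63), Hoxa3 (2.24), Hoxa4 (2.59) and Hoxa13 (2.96) had a promoter peak with 1-1067, and Hoxb7 and Hoxd1 in vector. Spi1 (3.02), Lmo2 (3.25), Lyl1 (3.04), Cdkn1a (2.53) and Rnf2 (2.72) were listed with 1-1067 and not in vector. Ribosomal protein genes counted 8 with 1-1067 and 7 in vector, with Rpl32 in both. No developmental regulator was listed in either, and mast cell genes counted 3 in vector (Prss34, Ms4a2 and Mitf) and 0 with 1-1067.

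The 34DN and 36EQ forms were compared with 1-1067, to ask what neutralizing charge does. Genes with a promoter peak only with 1-1067 numbered 1419 against 929 only with 34DN, and 1296 against 1146 only with 36EQ. At matched depth they were 1449 against 825 and 1361 against 949. With q of 0.05 or less the 36EQ comparison turned around, to 597 only with 1-1067 against 654 only with 36EQ. Peaks with 34DN numbered 0.841 times those of 1-1067 and 0.716 times at matched depth, and with 36EQ 0.964 and 0.745 times, neither matched ratio told from 1. At p of 1e-08 the matched ratios were 0.529 and 0.647, both below 1 beyond the error of the thinning. Of 34DN peaks 11.9% (11.05 to 12.8) met a peak of 1-1067, and of 36EQ peaks 13.1% (12.3 to 14.0).

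Promoter peaks of 1-1067 missing with 34DN were led by Tbc1d23 (fold 6.23), Sertad3 (5.71), the electron-transfer gene Etfdh (5.70), Srp54a (5.37), Pnn (5.27), Ankhd1 (5.14), Atp6v1d and Eif2s1 (5.10, shared). Those missing with 36EQ were led by Etfdh (5.70), the actin-nucleation gene Arpc3 (5.05), Sec11c (4.95), Srsf5 (4.93), Fndc8 and the repair gene Rad51d (4.83, shared), and Cct6a with Psph (4.80, shared). Listed with 34DN and not with 1-1067 were Cfap119 and the H2B ubiquitin ligase gene Rnf40 (6.11, shared), Taf8 (5.40), Cnot3 (5.26), Bckdha and Exosc5 (5.04, shared), Cep43 (5.02) and Abtb1 (5.003). Listed with 36EQ and not with 1-1067 were Rps19 (6.14), Fastkd1 (5.33), Fiz1 and Zfp524 (4.90, shared), Desi1 and the end-joining gene Xrcc6 (4.86, shared), Taf8 (4.85) and Creb3l2 (4.72).

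None of the 4 Hox genes listed with 1-1067 had a promoter peak with 34DN or 36EQ. Most genes lacked one too: of all 2003 genes with a promoter peak in 1-1067, 584 had one with 34DN and 707 with 36EQ. With q of 0.05 or less in both, 274 and 356 of 953 genes did. The list members named here were not filtered on q. Outside the promoter, 34DN had a peak in or within 2 kb of Hoxa3 (fold 2.88) and of Hoxa13 (2.93). Hoxd3 was the single Hox gene with a promoter peak in 34DN (fold 3.16), and 36EQ had none. Spi1, Itgam, Lmo2, Lyl1, Cdkn1a, Tnf and Rnf2 were also missing from both forms, as were the replication genes Mcm6, Mcm7 and Pcna. Of 20 interferon-stimulated genes, Stat2, Oasl2 and Irf7 were listed with 34DN, Ifi35, Isg15 and Bst2 with 36EQ, and 0 with 1-1067 or in vector, small counts that lay at percentile 91.4 for each form when depth was matched. Ribosomal protein genes counted 7 with each form. Over the 4 libraries of the set, 227 of 4547 genes with a promoter peak had one in all 4, 915 only with 1-1067, 574 only with 34DN, 764 only with 36EQ and 717 only in vector.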

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

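The tests of depth, of H2AK119ub peaks at shared ChIP regions and of spread between libraries were chosen only after the result was seen; the test of repeated sequence was chosen before.

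Many of the strongest ChIP peaks lay at the same places in all 4 ChIP libraries: of peaks with -log10 q of at least 5, 81.7% with BAP1 and 1-590, 53.1% with BAP1 and 10RA, 46.8% with ASXL1 and 1-590 and 58.0% with ASXL1 and 10RA met a peak in all 4. Regions that collect reads whatever the antibody could account for this, since 86.0% of the 86 shared regions (77.2 to 91.8) also had a peak in at least 1 of the 8 H2AK119ub libraries, and 17 regions had one in all 12 libraries. Repeated sequence remains open: 51.2% of the shared regions (40.8 to 61.4) had a median of 2 or more copies, against 12 of 200 regions found in a single library. A biological explanation, that BAP1 and ASXL1 bind the same sites in both constructs, would not need H2AK119ub peaks there, and it was not tested apart from these.

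More H2AK119ub peaks were listed in 1-590, 10RA and 25RA than in their vector, 1.61, 1.40 and 1.68 times as many. Depth could account for this at the authors' cutoff: thinned to the vector's background the ratios were 1.04, 0.923 and 1.06, each within the error of the thinning. At p of 1e-05, 1e-06 and 1e-08 they were 0.755, 0.758 and 0.829 for 1-590, 0.538, 0.438 and 0.292 for 10RA and 0.629, 0.529 and 0.385 for 25RA. The 10RA and 25RA values at these 3 p lie below 1 beyond the error of the thinning, an error that counts in the shortfall of thinned simulated peaks, while those of 1-590 lie within it. Fewer strong peaks with 10RA and 25RA than in vector at matched depth therefore remain, and with 1 library per condition their cause is open.

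More H2AK119ub peaks were listed in 1-1067 than in its vector, 1.10 times as many and 1.502 times at matched depth. A deeper library cannot account for this, since the background of 1-1067 was 0.743 times that of vector. Spread between libraries with no part of the construct remains open: the vector libraries of the sets differed 3.50 times in peak number, across batches, and each condition has 1 library. An effect of the construct might therefore be present but cannot be told from that spread.

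The 10RA list was longer than the 1-590 list for BAP1 (1.36 times) and shorter for ASXL1 (0.548 times), opposite directions in the ChIP of the 2 proteins as listed. With depth matched, at p of 0.001, the ratios were 1.03 and 1.00, each within the error of the thinning, and the difference was not tested between replicates. At p of 1e-08 they were 1.43, above 1 beyond that error with a lower bound of 1.04, and 0.963, within it. Peaks on unplaced sequences, used only in the comparison of peak numbers on all sequences, numbered 60 and 73 for BAP1 with 1-590 and 10RA and 91 and 76 for ASXL1, and 0 ChIP peaks were mitochondrial.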

How the results depend on the processing

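The tests at matched depth and with q of 0.05 or less were chosen only after the result was seen. Ratios that moved beyond 1.5 times or to the other side of 1, shares that left the first interval and percentiles that entered or left the outer 5% are given by setting; for each of these the cause was not tested. Of 42 ratios on the other side of 1, 24 had an interval without 1 (reversed) and 18 one that holds 1 (reversed, open). Depth limits every count, since background ran from 0.908 to 5.46 fragments per base, and these intervals hold no spread between libraries. At matched depth, the simulated error of the thinning applies to peak numbers only. With -log10 q of at least 5 in both, 1 of 12 pairs gave no ratio of promoter genes.

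For peak numbers, ratios are the first library over the second, and vector is the vector of the same set. With -log10 q of at least 5: BAP1 10RA over 1-590 2.13, 1-590 over vector 3.36, 10RA over 1-590 0.322, 25RA over 1-590 0.524 (reversed), 1-1067 over vector 1.73, 34DN over vector 1.53 (reversed), 36EQ over vector 2.48, 36EQ over 1-1067 1.44 (reversed). At matched depth and p of 1e-05: BAP1 10RA over 1-590 0.919 (reversed, open), ASXL1 10RA over 1-590 1.16 (reversed, open), 1-590 over vector 0.755 (reversed, open), 10RA over vector 0.538 (reversed), 25RA over vector 0.629 (reversed), 25RA over 1-590 0.833 (reversed, open), 1-1067 over vector 2.25, 34DN over vector 1.26 (reversed, open), 36EQ over 1-1067 0.589. With fold of at least 5: ASXL1 10RA over 1-590 0.966, 10RA over vector 0.589 (reversed), 25RA over vector 0.797 (reversed), 10RA over 1-590 0.390, 25RA over 1-590 0.528 (reversed), 1-1067 over vector 2.26, 34DN over vector 1.77 (reversed), 36EQ over vector 1.97. With q of 0.05 or less: ASXL1 10RA over 1-590 0.344, 34DN over vector 1.11 (reversed). At matched depth and p of 0.001: ASXL1 10RA over 1-590 1.000, 1-590 over vector 1.04, 10RA over vector 0.923 (reversed, open), 25RA over vector 1.06, 34DN over vector 1.08 (reversed, open). At matched depth and p of 1e-06: ASXL1 10RA over 1-590 1.02 (reversed, open), 1-590 over vector 0.758 (reversed, open), 10RA over vector 0.438 (reversed), 25RA over vector 0.529 (reversed), 10RA over 1-590 0.577, 25RA over 1-590 0.698 (reversed, open), 1-1067 over vector 2.47, 34DN over vector 1.33 (reversed, open), 34DN over 1-1067 0.539, 36EQ over 1-1067 0.609. At matched depth and p of 1e-08: ASXL1 10RA over 1-590 0.963, 1-590 over vector 0.829 (reversed, open), 10RA over vector 0.292 (reversed), 25RA over vector 0.385 (reversed), 10RA over 1-590 0.353, 25RA over 1-590 0.465 (reversed), 1-1067 over vector 3.08, 34DN over vector 1.63 (reversed, open), 36EQ over vector 1.99, 34DN over 1-1067 0.529. By covered bases: 25RA over 1-590 0.860 (reversed), 36EQ over 1-1067 1.02 (reversed, open). Values on the same side of 1 and within 1.5 times numbered 4 with -log10 q of at least 5, 12 for all sequences, 10 by covered bases, 7 at matched depth and p of 0.001, 3 at matched depth and p of 1e-05, 2 at matched depth and p of 1e-06, 2 at matched depth and p of 1e-08, 4 with fold of at least 5, 12 for merged peaks, 10 with q of 0.05 or less.

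For shared peaks, values are the percent of the first library's peaks that meet the second. With a reciprocal overlap of 50%: BAP1 1-590 in 10RA 3.08, ASXL1 10RA in 1-590 3.56, vector in 1-590 37.9, vector in 10RA 30.2, vector in 25RA 36.1, 10RA in 1-590 29.1, 1-590 in 25RA 30.2, vector in 1-1067 7.12, 34DN in vector 6.50, vector in 36EQ 7.07, 34DN in 1-1067 8.03, 36EQ in 1-1067 8.86, BAP1 1-590 in ASXL1 1-590 3.08, ASXL1 10RA in BAP1 10RA 2.66. With a gap of up to 1 kb: BAP1 1-590 in 10RA 4.98, ASXL1 10RA in 1-590 6.15, vector in 1-590 59.7, vector in 10RA 48.5, vector in 25RA 55.8, 10RA in 1-590 48.6, 1-590 in 25RA 49.7, vector in 1-1067 13.5, 34DN in vector 12.3, vector in 36EQ 12.7, 34DN in 1-1067 14.0, 36EQ in 1-1067 15.6, BAP1 1-590 in ASXL1 1-590 5.49, ASXL1 10RA in BAP1 10RA 5.21. With -log10 q of at least 5 in both: BAP1 1-590 in 10RA 80.0, ASXL1 10RA in 1-590 80.7, vector in 1-590 84.3, vector in 10RA 47.1, vector in 25RA 65.2, 10RA in 1-590 74.9, 1-590 in 25RA 36.2, vector in 1-1067 46.8, 34DN in vector 31.6, vector in 36EQ 51.6, 34DN in 1-1067 42.1, 36EQ in 1-1067 31.2, BAP1 1-590 in ASXL1 1-590 78.3, ASXL1 10RA in BAP1 10RA 62.5. With q of 0.05 or less in both: BAP1 1-590 in 10RA 25.2, ASXL1 10RA in 1-590 30.2, vector in 1-590 58.8, vector in 10RA 45.3, vector in 25RA 52.9, 10RA in 1-590 44.6, vector in 1-1067 19.3, 34DN in vector 14.6, vector in 36EQ 19.6, 34DN in 1-1067 20.4, 36EQ in 1-1067 19.2, BAP1 1-590 in ASXL1 1-590 25.4, ASXL1 10RA in BAP1 10RA 27.3. With lists of the same length: vector in 1-590 47.7, vector in 10RA 37.5, vector in 25RA 41.3, 10RA in 1-590 40.9, 1-590 in 25RA 41.9. Values inside the first interval numbered 1 with q of 0.05 or less in both, 9 with lists of the same length.

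For promoter genes, values are genes only in the first library over genes only in the second. With lists of the same length: BAP1 10RA over 1-590 1.06, ASXL1 10RA over 1-590 0.764, 1-590 over vector 2.51, 10RA over vector 0.654 (reversed), 25RA over vector 0.867 (reversed). With q of 0.05 or less in both: BAP1 10RA over 1-590 2.8, 34DN over vector 1.1974 (reversed), 36EQ over vector 1.84, 36EQ over 1-1067 1.10 (reversed, open). With -log10 q of at least 5 in both: ASXL1 10RA over 1-590 0.167, 1-590 over vector 29.2, 10RA over vector 0.882 (reversed), 10RA over 1-590 0.0412, 25RA over 1-590 0.111, 1-1067 over vector 3.25, 34DN over vector 3.09 (reversed), 36EQ over vector 5.84, 34DN over 1-1067 1.02 (reversed, open), 36EQ over 1-1067 2.09 (reversed). At matched depth and p of 0.001: ASXL1 10RA over 1-590 0.707, 1-590 over vector 1.80, 10RA over vector 0.481 (reversed), 25RA over vector 0.749 (reversed), 34DN over vector 1.06 (reversed, open). With promoters of 1 kb on each side: 10RA over vector 0.967 (reversed, open). Values on the same side of 1 and within 1.5 times numbered 1 with -log10 q of at least 5 in both, 11 with promoters of 1 kb on each side, 12 with promoters of 5 kb on each side, 7 at matched depth and p of 0.001, 8 with q of 0.05 or less in both, 7 with lists of the same length.

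For the gene lists, values are percentiles in the 1-590 set. With promoters of 1 kb on each side: in vector, Hox 0.620, myeloid 88.9, developmental 0.0700, BAP1 complex 93.9, and in 1-590, Hox 0.165, ribosomal 98.5, and in 10RA, Hox 61.9, myeloid 98.0, mast cell 93.0, and in 25RA, HSPC 0.295, developmental 0.435. At matched depth and p of 0.001: in 1-590, myeloid 95.019, mast cell 96.951, interferon 94.3, MYC 90.8, and in 10RA, Hox 92.5, mast cell 87.4. Against unmatched random lists: in vector, HSPC 24.8, myeloid 36.0, mast cell 44.8, Polycomb 98.2, ribosomal 99.985, and in 1-590, HSPC 99.57, myeloid 23.6, mast cell 46.1, developmental 76.5, cell cycle 99.03, Polycomb 99.74, BAP1 complex 99.54, interferon 65.7, ribosomal 100, and in 10RA, erythroid 1.84, mast cell 42.5, developmental 99.905, ribosomal 98.7, MYC 99.4, and in 25RA, Hox 99.94, cell cycle 98.6, Polycomb 99.2, BAP1 complex 99.2, ribosomal 98.6, MYC 97.6. With promoters of 5 kb on each side: in vector, HSPC 32.9, stromal 98.5, BAP1 complex 95.5, and in 1-590, HSPC 99.4, lymphoid 98.4, developmental 15.9, Polycomb 97.9, cytokine 96.1, MYC 97.025, and in 10RA, HSPC 97.7, myeloid 99.555, developmental 99.945, and in 25RA, Hox 99.965, myeloid 99.4, lymphoid 99.85, mast cell 97.6. Percentiles on the same side numbered 53 with promoters of 1 kb on each side, 48 with promoters of 5 kb on each side, 58 at matched depth and p of 0.001, 39 against unmatched random lists.

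For ChIP peaks that carry an H2AK119ub peak of the same construct, values are percent. With a gap of up to 1 kb: BAP1 1-590 2.49, BAP1 10RA 3.45, ASXL1 1-590 3.78, ASXL1 10RA 3.10. With lists of the same length: BAP1 1-590 0.560, BAP1 10RA 0.903, ASXL1 1-590 0.597, ASXL1 10RA 0.938. With q of 0.05 or less in both: BAP1 1-590 8.78, BAP1 10RA 5.28, ASXL1 1-590 6.08, ASXL1 10RA 8.83.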

Other observations

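Among the 16 gene lists, local background in each library of the 1-590 set was highest at Hox promoters, followed by developmental regulators. The median level at Hox promoters with a peak was 7.27 times the genome background with 10RA and 6.41 with 25RA, against 9.21 with 1-590. At all promoters with a peak it was 2.16, 2.22 and 2.47. For developmental regulators it was 6.004 with 10RA and 6.05 with 25RA. Ribosomal protein promoters lay at 1.85 with 10RA and 1.73 with 25RA. The levels of HSPC regulators lay between, at 3.62 and 3.04.

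The Hoxa genes, taken with 2 kb on each side, had few ChIP peaks. With 1-590, the ASXL1 library had 1 at Hoxa10 and the BAP1 library 1 at Hoxa13, neither at the promoter nor touching an exon. Mast cell and basophil genes with a promoter peak lay high among matched random lists in vector (percentile 99.7), 1-590 (99.98) and 10RA (99.1) of the 1-590 set as listed. At matched depth the percentiles of 1-590 and 10RA were 96.95 and 87.4. In 25RA only 3 of 13 genes had a promoter peak as listed, and its percentile at matched depth was 55.0. Among lists not matched for CpG content vector, 1-590 and 10RA were at 44.8, 46.1 and 42.5, and with promoters of 1 kb on each side 10RA was at 93.0.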
